A study of Homo sapiens with 22 samples.

How the data were processed

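The values were normalized array intensities deposited by the authors, 1 log2 value per probe set and array, which the submitters' processing notes describe as made with RMA in Partek software; its version is not given in the sources used here. The table held 33297 probe sets and 22 arrays. A probe table listed 21236 of them, 19181 with 1 gene symbol and 2055 with several. The other 12061 were tested apart and counted without names. Y-linked genes and the X-inactivation transcripts, 25 probe sets, were left out. For each of the 894 genes with several probe sets the one with the highest mean was used, which left 17934 genes.

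Groups followed the sample titles. For 8 samples, not listed here, the cell type read from the description was not that of the source name, and the titles were used. Sample numbers of the titles shared between groups were read as donors. The array labelled resting naive replicate 6 stayed in its labelled group in every fit that did not leave it out.

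Genes were tested with limma 3.58.1 in R 4.3.3. One linear model with a mean for each of the 4 groups gave 5 contrasts: memory minus naive at rest and at 48 h, 48 h minus rest in each cell type, and their difference, the interaction. Standard errors (SE) came from the moderated variances, and p values were adjusted by the Benjamini-Hochberg method over the 17934 genes of a contrast, with 0.05 as the threshold. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the table and drew the plots.

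A self-test on simulated arrays, made of each gene's mean and normal noise with its residual SD, added known differences to 66 or 67 genes per size. At a log2 difference of 0.5, 1 and 2 it recovered 53.7%, 92.5% and 100% at rest, 35.8%, 91.0% and 97.0% at 48 h, 26.9%, 86.6% and 98.5% for activation of naive cells, 44.8%, 97.0% and 100% for activation of memory cells and 14.9%, 76.1% and 95.5% for the interaction. False calls numbered 8, 9, 6, 12 and 10.

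There were 26 gene lists and 10 lists of cell type markers, fixed before the values were seen, with 549 members of which 495 were measured. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. None of the 4 gamma delta T cell markers was measured. "Adjusted over the list alone" means that p values were adjusted over the members of 1 list.

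Genes were named by a rule fixed beforehand: up to 6 genes per direction and contrast by size, among those whose groups did not overlap (except for the interaction), up to 2 per list (1 for the interaction), and CCR7, IL2RA, CD69, MKI67, IL2, IFNG, DNMT1 and DNMT3A in every contrast, 106 symbols in all with those of the rule applied again without the array labelled naive replicate 6. For pairs of resting and activated arrays, or of memory and naive arrays, the number of donors with the direction of the group difference was counted.

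The alternatives were donors as fixed or random blocks, the 4 donors with all 4 arrays, the groups of a contrast alone, a trended and robust variance prior, array weights, a further quantile normalization, subtraction of array medians, a filter on dim genes, every probe set of a gene, a 2-fold minimum and each array left out in turn. Fits without 4 memory arrays with high platelet markers and with a monocyte score as a covariate were chosen after seeing the data. So was the fit with blocks but without the array labelled naive replicate 6. The 4 arrays were resting memory replicates 2, 5 and 6 and memory replicate 2 at 48 h. They had the highest values of the platelet markers PPBP and PF4. By the mean of the 8 platelet markers, resting naive replicate 5, which was kept, lay above memory replicate 2 at 48 h (7.45 against 6.90). Raw intensities were not used here.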

Results

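Transcript levels were measured on whole-transcript arrays in human CD4 T cells that had been purified as naive or memory cells by negative selection with magnetic beads. Cells were taken at rest or 48 h after activation with beads that engage CD3 and CD28, the antigen receptor complex and its main costimulatory receptor. There were 6 arrays of resting naive cells, 7 of resting memory cells, 4 of naive cells at 48 h and 5 of memory cells at 48 h, 22 in all. Sample numbers shared between groups were read as 7 donors. Without the array labelled resting naive replicate 6, described below, the deviations of 2 arrays with the same number from their group means correlated across genes at r of 0.113 to 0.499 over 26 pairs, against a median of -0.0697 and a highest value of 0.396 between numbers; genes are not independent replicates. Array medians lay between 5.38 and 5.61 on the log2 scale. A difference from a group mean under 5.38, where the signal nears background, is a lower bound, as is marked below. The number of arrays limits the precision.

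Activation separated the arrays along the first principal component, which held 53.6% of the variance, and cell type along the second, which held 16.9%. The second component did not hold cell type alone. The resting memory arrays, from 10.3 (replicate 4) to 39.2 (replicate 6), lay along it in the order of their mean of the monocyte markers, described below. The array labelled resting naive replicate 6 lay among the resting memory arrays. Across genes it correlated with the 7 resting memory arrays at 0.977 to 0.991 and with the other 5 resting naive arrays at 0.963 to 0.972. It stayed in its labelled group, so differences at rest below include it, and values without it are given where they change a statement.

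**Figure D1:**
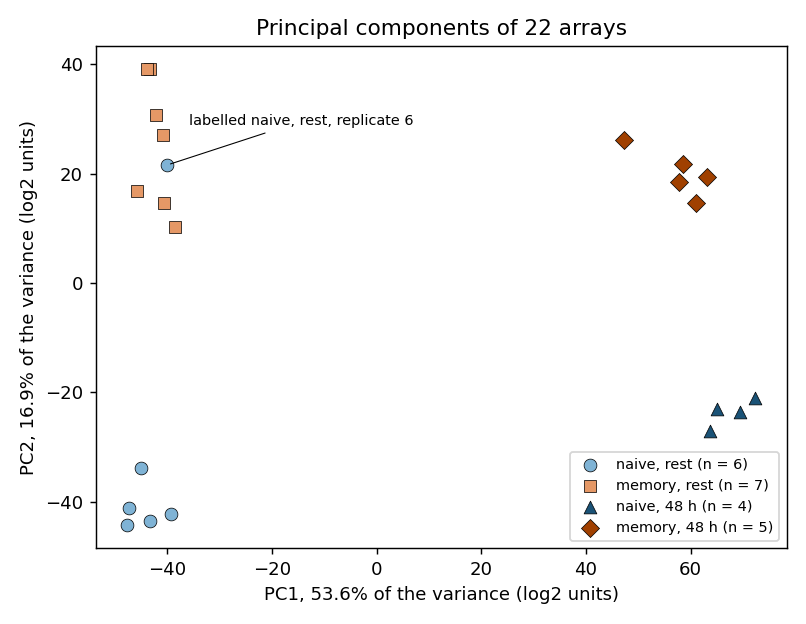
Principal components 1 and 2 of the 22 arrays, in log2 units, with 1 point per array and 1 symbol per group. Resting and activated arrays separated along component 1 (53.6% of the variance), and the array labelled resting naive replicate 6 lay with the resting memory arrays.

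The first question was how memory and naive CD4 cells differ at rest. Resting memory cells had more transcript of receptors that guide T cells into tissues: CCR2, a receptor for inflammatory chemokines, was at least 17.2-fold higher (log2 difference 4.10 ± 0.54 SE, n = 7 and 6, from a naive mean of 5.25) and CCR4, a receptor of skin-homing cells, was higher by 3.46 ± 0.54. KLRB1, the lectin-like receptor CD161 of IL-17-producing and innate-like T cells, was higher by 3.46 ± 0.50, and CCL5, a chemokine stored by experienced T cells, 7.77-fold higher (2.96 ± 0.31). NOG, the BMP antagonist Noggin and a marker of naive CD4 cells, was 9.60-fold lower (-3.26 ± 0.49). Without the array labelled naive replicate 6 the log2 differences were 4.78 for CCR2, 4.21 for CCR4, 4.12 for KLRB1 and -3.92 for NOG. On the resting memory arrays CCR2 was 8.96 to 9.71. It was lowest on replicate 4, where the mean of the monocyte markers, described below, was also lowest. Whether monocytes added to the CCR2 signal was not tested. CCR2, CCR4, KLRB1 and CCL5 were higher and NOG lower in at least 5 of the 6 donors with both arrays, with adjusted p between 3.0e-05 and 0.000233. In counts of donors at rest, here and below, the 6 pairs include the array labelled naive replicate 6.

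Of 24 memory T cell genes measured, 23 were higher in resting memory cells and none was lower (median log2 difference 1.77, camera adjusted p = 2.0e-26); adjusted over the list alone, 24 were higher. Of 16 naive T cell genes, 11 were lower and 5 did not pass the test (median -0.71, adjusted p = 1.9e-09), and 13 were lower when adjusted over the list alone. LRRN3 was 5.70-fold lower, FHIT 3.25-fold lower and CCR7, which directs cells to lymph nodes, 1.62-fold lower. Among 15 chemokine and homing receptors 11 were higher (median 1.65, adjusted p = 3.0e-12), 13 when adjusted over the list alone. Of 17 T helper lineage transcription factors 11 were higher (median 0.89, adjusted p = 7.6e-10; 13 higher and 1 lower adjusted over the list alone), among them PRDM1, which encodes Blimp-1, at 7.64-fold (log2 difference 2.93, and 3.53 without the array labelled naive replicate 6) and MAF, a regulator of IL-4, IL-10 and IL-21, at 5.36-fold. With an estimated correlation these 4 lists each had adjusted p = 0.0599.

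Regulatory T cell genes were higher in 9 of 12 cases (median 1.41, adjusted p = 8.0e-11; 11 adjusted over the list alone), with the checkpoint receptor TIGIT 5.92-fold and IL2RA, the high-affinity IL-2 receptor chain, 5.02-fold higher. Cytotoxic genes were higher in 7 of 14 cases (median 0.97, adjusted p = 3.5e-07; 8 adjusted over the list alone), including GZMA at 4.48-fold and CST7 at 5.09-fold. Both lists had adjusted p = 0.0599 with an estimated correlation. Cytokine genes were mostly not different at rest: 4 of 17 were higher (median 0.10, adjusted p = 0.0203, and adjusted p = 0.232 with an estimated correlation; 4 adjusted over the list alone). IFNG, encoding interferon gamma, was at least 6.73-fold higher (2.75 ± 0.56, adjusted p = 0.0020) in 5 of 6 donors. IL2 differed by 0.43 ± 0.24 (adjusted p = 0.262). With donors as blocks and without the array labelled naive replicate 6, IL2 was higher by 0.67 (adjusted p = 0.0180).

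Genes of the cell cycle were also higher in resting memory cells, from low levels. Of 18 mitosis genes 12 were higher (median 0.95, adjusted p = 2.0e-10; 14 adjusted over the list alone) and of 22 DNA replication genes 10 (median 0.33, adjusted p = 1.0e-06; 14 adjusted over the list alone). MKI67, the proliferation marker Ki-67, was at least 4.60-fold higher (2.20 ± 0.49, adjusted p = 0.0040) in 6 of 6 donors. In the pair with the array labelled naive replicate 6 the levels were close, 7.39 in memory and 7.14 in that array. Both lists had adjusted p = 0.130 with an estimated correlation. Among 17 genes of the DNA methylation machinery, 3 were higher and 1 was lower (median 0.01, adjusted p = 0.823; 3 and 2 adjusted over the list alone). UHRF1, which guides DNMT1 to newly replicated DNA, was at least 2.35-fold higher, GADD45A was higher by 0.59 on the log2 scale and the de novo methyltransferase DNMT3A was 1.33-fold lower (-0.42 ± 0.11, adjusted p = 0.0139). The maintenance methyltransferase DNMT1 differed by 0.08 ± 0.13 (adjusted p = 0.750).

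Genes of other blood cells moved with the memory group at rest. HLA-DRA, MMP8, CRISP3 and S100A12 were named at rest after their values were seen, by the naming rule applied again without the array labelled naive replicate 6. HLA-DRA, a class II antigen-presentation gene that dendritic cells, monocytes and activated T cells express, was higher by 5.00 ± 0.82 on the log2 scale. It was still higher in memory cells at 48 h, by 3.16 (limma adjusted p = 0.0240 over every probe set). Its change with activation in memory cells was -1.89 (adjusted p = 0.0858). MMP8 and CRISP3, proteins of neutrophil granules, were 31.5-fold and 24.6-fold higher, and S100A12, a protein of neutrophils and monocytes, 26.4-fold. In resting naive cells MMP8, CRISP3 and S100A12 averaged 4.16, 5.05 and 5.30, under the array medians, so these folds are lower bounds. Without that array the log2 differences were 5.91 for HLA-DRA, 6.01 for MMP8, 5.57 for CRISP3 and 5.68 for S100A12, and MMP8 had 5.64 without memory replicate 4 at rest. Of 11 monocyte markers 6 were higher (median 1.80, adjusted p = 2.0e-07), of 5 dendritic cell markers 3 (median 2.09, adjusted p = 0.000279) and 3 of 4 neutrophil markers (mean 1.37). The monocyte and dendritic lists had adjusted p = 0.104 and 0.111 with an estimated correlation. None of 8 platelet markers passed alone, yet their median was 1.53 (adjusted p = 0.00714, and 0.424 with an estimated correlation). CD14, the classical monocyte marker, differed by 0.70 on the log2 scale and averaged 5.57 in resting memory cells, near the array medians.

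**Figure D2:**
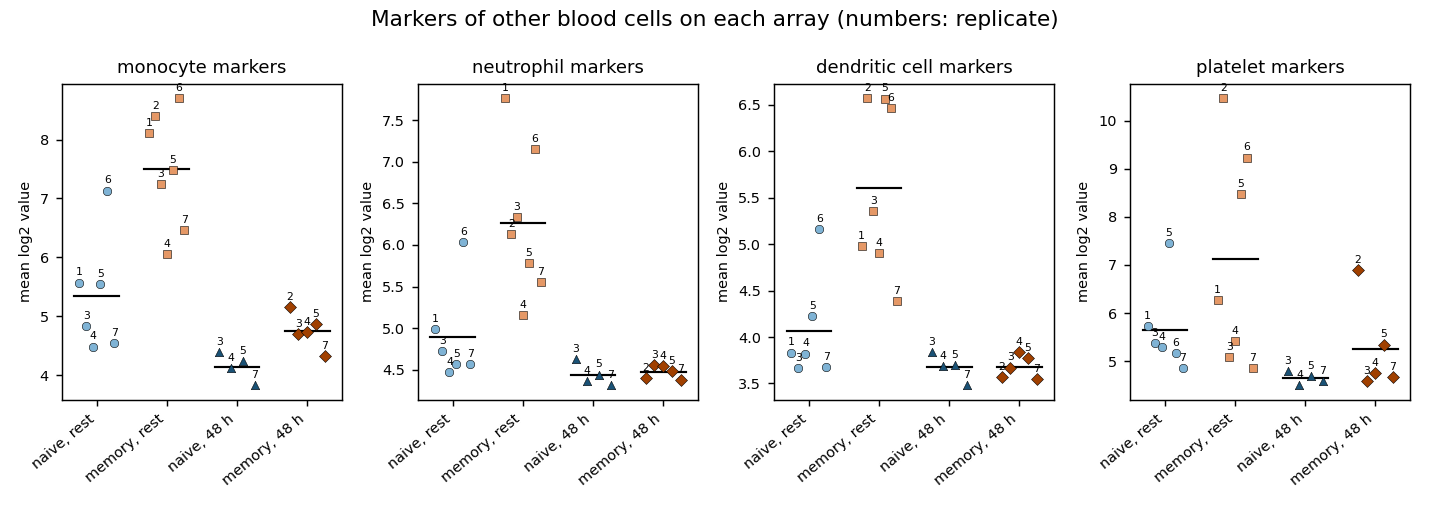
Mean log2 value of the monocyte, neutrophil, dendritic cell and platelet markers on each array, with 1 point per array, the replicate number beside it and a line at the group mean. Resting memory arrays had the highest mean of each marker set, and activated arrays were low except replicate 2 of the memory cells at 48 h for platelet markers.

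In all, 2292 of 17934 genes differed at rest at an adjusted p under 0.05, 1489 higher and 803 lower in memory cells, and 569 of the higher and 94 of the lower ones differed at least 2-fold. The groups did not overlap at all in 233 of the 17934 genes, where chance gives 0.117%, about 20.9, and 202 of the 233 also passed the test. The array labelled naive replicate 6 can only lower this count, and no count without it is given here. NOG, for example, had 6.22 on it, 6.02 to 6.67 on the resting memory arrays and 9.97 to 10.35 on the other naive arrays. The count of genes past the threshold, 2292 with all arrays, was 3409 without the array labelled naive replicate 6, and 2279 genes were shared. The count was 995 without the 4 memory arrays with high platelet markers and 3447 with array weights. With a monocyte score as a covariate it was 0, and 1032 genes had an unadjusted p under 0.05 in limma against 4751 before. The score itself differed between the groups (means 6.01 in naive and 8.72 in memory cells). The median SE at rest rose from 0.123 to 0.191 in that fit, which kept the array labelled naive replicate 6. It therefore cannot tell how much of the difference at rest came from monocyte transcripts. The share of higher genes depended on scaling: it was 65.0%, 48.1% after a further quantile normalization and 35.7% after subtraction of array medians, which moved the median of all genes by -0.115 at rest, by -0.145 for activation in naive cells and by 0.128 for the interaction.

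The second question was how the cell types differ 48 h after activation. Memory cells then expressed the cytokines of T helper effector cells far above naive cells. IL17A was 60.8-fold higher (5.93 ± 0.29 SE, n = 5 and 4), IL22 42.9-fold (5.42 ± 0.33), IL3 30.8-fold (4.94 ± 0.34), IFNG 23.1-fold (4.53 ± 0.67, and 5.39 without naive replicate 5 at 48 h) and the type 2 cytokine IL13 21.9-fold (4.45 ± 0.19). Each was higher in 4 of the 4 donors with both arrays, with adjusted p between 6.1e-13 and 4.4e-05. In naive cells at 48 h IL17A, IL22 and IL3 averaged 5.02, 3.65 and 4.74, under the array medians, so their folds are lower bounds. IL2 did not separate the cell types (0.08 ± 0.29, adjusted p = 0.909). MAF was 38.4-fold higher and PRDM1 21.2-fold.

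Of 17 cytokine genes 15 were higher in activated memory cells and none lower (median 2.09, camera adjusted p = 1.9e-22; 15 adjusted over the list alone). Of 11 chemokines 8 were higher (median 1.80, adjusted p = 3.9e-09; 8 adjusted over the list alone), with CCL4 at 21.4-fold and CCL3 at 17.5-fold. Of 14 cytotoxic genes 9 were higher (median 1.93, adjusted p = 2.4e-10; 9 adjusted over the list alone), led by the granzyme genes GZMK at 19.5-fold or more and GZMA at 8.81-fold. Of the CD8 T cell markers, looked at after their values were seen, CD8A averaged 7.49 in memory and 6.55 in naive cells (0.93 ± 0.39, adjusted p = 0.104) after a rise of 2.33 ± 0.34 in memory cells (adjusted p = 7.0e-06), with 8.80 in memory replicate 2 and 6.79 to 7.77 in the other 4 arrays. CD8B was lower in memory cells (-0.83 ± 0.20, adjusted p = 0.00406) and did not move in them with activation (-0.02 ± 0.17, adjusted p = 0.948). The memory means of CD8A at rest and of CD8B lay under 5.38. Whether CD8 T cells added to the cytotoxic genes was not tested. Costimulatory and inhibitory receptors were higher in 13 and lower in 2 of 17 cases (median 1.43, adjusted p = 8.1e-09; the same numbers adjusted over the list alone), and the TNF receptor family members TNFRSF18 and TNFRSF4 were 5.47-fold and 5.27-fold higher. Of 20 cytokine receptors 12 were higher and 1 lower (median 0.70, adjusted p = 1.6e-08; 13 and 1 adjusted over the list alone), the IL-1 decoy receptor IL1R2 by 9.60-fold. These 5 lists also passed with an estimated correlation.

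Memory T cell genes were higher in 20 of 24 cases (median 1.78, adjusted p = 2.6e-23; 23 adjusted over the list alone), T helper lineage transcription factors in 11 of 17 (median 1.06, adjusted p = 1.0e-11; 12 adjusted over the list alone) and homing receptors in 12 of 15 (median 1.75, adjusted p = 4.6e-11; 12 adjusted over the list alone), and all 3 lists passed with an estimated correlation. CXCR3, the receptor of T helper 1 cells, was 7.94-fold higher. Regulatory T cell genes were higher in 9 of 12 cases (median 1.72, adjusted p = 8.1e-09, and adjusted p = 0.0683 with an estimated correlation; 9 adjusted over the list alone), and CCR8 was at least 5.85-fold higher. Naive T cell genes split, with 5 higher and 6 lower of 16 (median -0.45, adjusted p = 0.953; 5 and 8 adjusted over the list alone). NOG was 7.38-fold and the adhesion receptor PECAM1 5.32-fold lower. CCR7 differed by -0.44 ± 0.19 (adjusted p = 0.116, and 0.0277 with donors as blocks). Without the array labelled naive replicate 6 at rest the difference was the same and its adjusted p was 0.0316. It was -0.56 (adjusted p = 0.0433) without memory replicate 2 at 48 h.

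DNA replication genes were lower in activated memory cells in 16 of 22 cases (median -0.73, adjusted p = 7.0e-09, and adjusted p = 0.0683 with an estimated correlation; 18 adjusted over the list alone) and mitosis genes in 9 of 18 (median -0.84, adjusted p = 3.4e-05, and adjusted p = 0.345 with an estimated correlation; 11 adjusted over the list alone). Of the mitosis genes 16 were lower without the array labelled naive replicate 6 at rest, with the same median of -0.84. That array enters a comparison at 48 h only through the variance shared by all groups. Mitosis genes lower in memory cells numbered 7 (median -0.61) without memory replicate 2 at 48 h and 6 (median -0.77) without naive replicate 3 at 48 h. One-carbon and nucleotide synthesis genes were lower in 16 of 20 cases (median -0.68, adjusted p = 2.0e-09; 17 adjusted over the list alone) and ribosome biogenesis genes lower in 15 and higher in 1 of 19 (median -0.67, adjusted p = 2.7e-09; 17 and 1 adjusted over the list alone). Both of the latter passed with an estimated correlation. Glycolysis genes were higher in 1 and lower in 1 of 17 cases (adjusted p = 0.675), cholesterol synthesis genes higher in 3 and lower in 1 of 14 (adjusted p = 0.252), and none of 15 ribosomal protein genes differed (adjusted p = 0.922). MKI67 differed by -0.57 ± 0.59 (adjusted p = 0.600) and was lower in 2 of 4 donors, with -0.17 without memory replicate 2 at 48 h. Of 17 genes of the DNA methylation machinery 2 were higher and 4 lower (median -0.11, adjusted p = 0.479), with UHRF1 2.32-fold lower and GADD45A 1.92-fold higher. DNMT1 was 1.37-fold lower (-0.45 ± 0.15, adjusted p = 0.0374) in 4 of 4 donors. Its call was lost without any 1 of naive replicates 3, 4 and 7 at 48 h (-0.43, -0.49 and -0.35) or memory replicates 2 and 5 at 48 h (-0.37 and -0.38), with adjusted p of up to 0.148. DNMT3A differed by -0.33 ± 0.13 (adjusted p = 0.0836, and 0.0392 with donors as blocks).

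**Figure D3:**
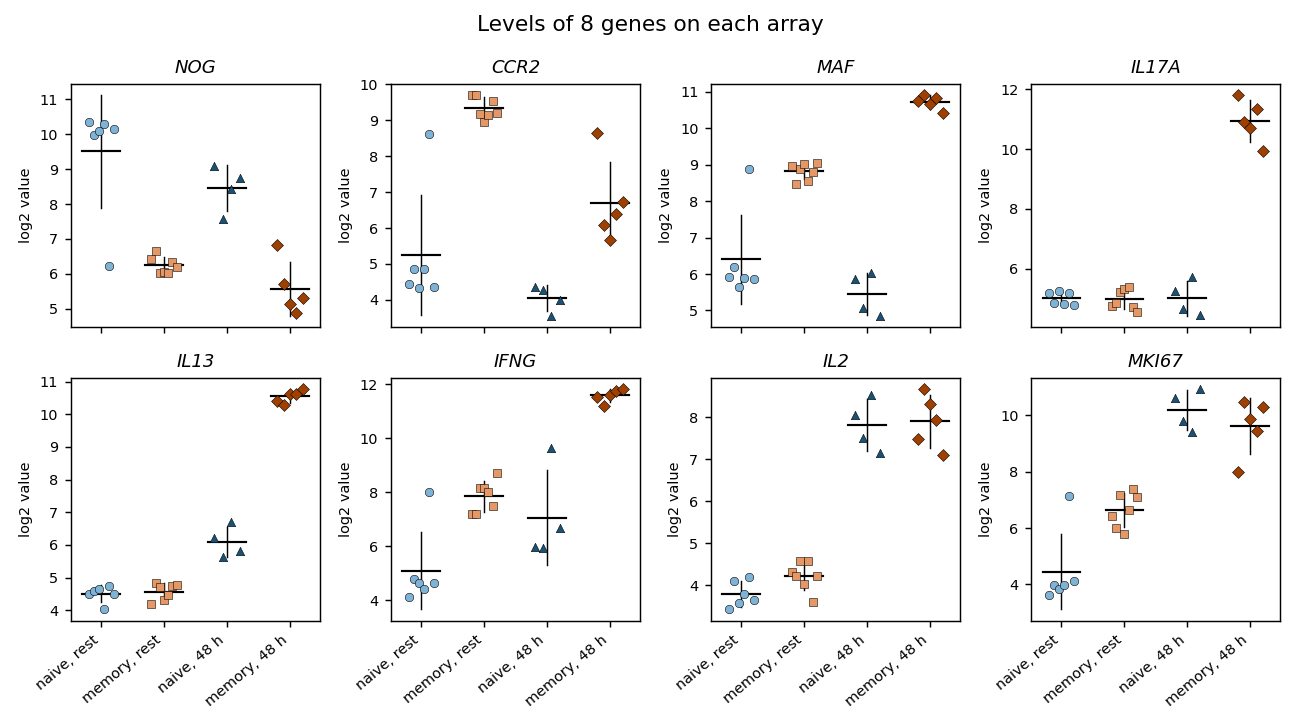
Log2 values of 8 genes on each array, with 1 point per array, a horizontal line at the group mean and a vertical line of 1 SD to each side. IL17A averaged 10.9 in memory cells at 48 h and 5.02 or less in the other groups, and 1 resting naive array, replicate 6, had memory-like levels of NOG, CCR2 and MAF.

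A total of 3845 genes differed at 48 h, 1545 higher and 2300 lower in memory cells, with 544 and 249 of them at least 2-fold. The groups did not overlap in 3414 of all genes, where chance gives 1.59%, about 285, and 2856 of the 3414 also passed the test. Of the 544 genes at least 2-fold higher at 48 h, 309 were already higher at rest, 7 were lower and 228 did not pass the test at rest. Of those 228, 112 had mean levels below 6.21, the median of all values, in both resting groups. Of the 249 genes at least 2-fold lower at 48 h, 62 were already lower at rest, 16 were higher and 171 did not pass, 111 of them with such low levels.

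The differences at rest and at 48 h overlapped in part. Memory cells were higher at both times in 524 genes, where independent sets would share 128, and lower at both times in 238, where they would share 103, and 107 genes went opposite ways. CCL5, MAF, PRDM1 and KLRB1 were among those higher at both times and NOG, ADD2 and AK5 among those lower at both. Log2 differences correlated across genes at r = 0.403 (Spearman 0.236), and genes are not independent replicates. The count of 762 genes with the same direction was 1146 without the array labelled naive replicate 6 at rest and 1180 with donors as blocks. It was 387 without the 4 memory arrays with high platelet markers, and 0 with the monocyte score as a covariate.

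The third question was what activation changed in each cell type. In naive cells the machinery of division rose from levels near or below the array medians, where folds are lower bounds: DTL, a cell cycle ubiquitin ligase adaptor, rose 128-fold (SE 0.39 on the log2 scale, n = 4 and 6), CDK1 rose 93.0-fold (6.54 ± 0.31) and TYMS, thymidylate synthase, 79.1-fold (6.31 ± 0.38). In memory cells CDK1 rose at least 28.7-fold (4.84 ± 0.28, n = 5 and 7) and TYMS 16.8-fold (4.07 ± 0.34), while the largest rises, also from levels under the array medians, were in ZBED2 at 92.7-fold, CCL3 at 64.0-fold, IL13 at 62.8-fold and IL17A at 62.3-fold. KLF2, a factor of quiescent circulating T cells, fell in both, by 3.87 ± 0.17 on the log2 scale in naive and by 3.46 ± 0.15 in memory cells. Each change was seen in 4 of 4 naive or 5 of 5 memory pairs, with adjusted p of 2.0e-09 or less.

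All 22 DNA replication genes and all 18 mitosis genes rose in both cell types. The median rise of the replication genes was 3.80 in naive and 2.65 in memory cells (camera adjusted p = 2.3e-25 and 2.4e-23), and that of the mitosis genes 4.86 and 2.93 (adjusted p = 6.3e-18 and 7.4e-14, and 0.0625 and 0.0891 with an estimated correlation). Glycolysis genes rose in 16 of 17 cases in each cell type (medians 1.22 and 1.18, adjusted p = 1.3e-12 and 1.3e-12), with ALDOC up 6.23-fold and 7.27-fold. One-carbon and nucleotide synthesis genes rose in 17 and 15 of 20 cases (medians 1.63 and 1.09, adjusted p = 6.0e-13 and 9.4e-10). The serine synthesis enzymes PHGDH and PSAT1 rose by 3.81 and 3.78 on the log2 scale in naive and by 3.31 and 2.78 in memory cells. Cholesterol synthesis genes rose in 12 and 13 of 14 cases, and 1 fell in each (medians 1.26 and 1.52, adjusted p = 3.5e-07 and 1.5e-08), with FDPS up 4.23-fold and 3.30-fold. Quiescence genes fell in 12 and 13 of 14 cases (medians -1.30 and -0.95, adjusted p = 4.5e-10 and 4.3e-08). Apart from the mitosis list, these lists passed with an estimated correlation, and adjusted over the list alone the counts were the same except for 14 quiescence genes in naive cells.

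Amino acid transport and stress response genes rose in 12 and 10 of 15 cases and fell in 2 and 2 (adjusted p = 7.1e-06 and 0.000140; 13 and 11 rose adjusted over the list alone), and the memory list had adjusted p = 0.0805 with an estimated correlation. SLC7A5, the transporter of large neutral amino acids, rose by 4.29 and 3.39 on the log2 scale. Ribosome biogenesis genes rose in 16 and fell in 1 of 19 cases in naive cells (adjusted p = 4.4e-05, and adjusted p = 0.144 with an estimated correlation) and rose in 9 and fell in 2 in memory cells (adjusted p = 0.140). Activation transcription factors rose in 15 and 13 of 23 cases and fell in 6 and 6 (adjusted p = 0.0115 and 0.00196, and 0.412 and 0.317 with an estimated correlation). EGR1 rose 14.6-fold and 21.1-fold, and FOS, an early factor, fell by 4.43 and by 4.18. Naive T cell genes fell in 11 of 16 cases in naive cells (adjusted p = 2.7e-05, and 0.206 with an estimated correlation) and fell in 7 and rose in 3 in memory cells (adjusted p = 0.0543, and 0.0328 with donors as blocks or 0.0385 without the array labelled naive replicate 6 at rest).

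T cell cytokines rose in 14 and fell in 2 of 17 cases in memory cells (median 3.68, adjusted p = 2.8e-10) and rose in 6 and fell in 1 in naive cells (median 0.64, adjusted p = 0.0777, and 0.0354 without the array labelled naive replicate 6 at rest). The counts adjusted over the list alone were the same, and the memory list passed with an estimated correlation. IL2 rose at least 16.4-fold in naive and 12.9-fold in memory cells, from resting means of 3.78 and 4.22. IFNG rose 13.3-fold in memory cells and at least 3.87-fold in naive cells (1.95 ± 0.65, adjusted p = 0.0176), where the value was 1.09 (adjusted p = 0.141) without naive replicate 5 at 48 h. Chemokines rose in 8 of 11 cases in memory cells (median 1.58, adjusted p = 4.9e-05, which passed with an estimated correlation) and in 5 in naive cells, where 1 fell (adjusted p = 0.143). TNFRSF9, the costimulatory receptor 4-1BB, rose 46.8-fold (a lower bound) and 36.1-fold and IL2RA 22.1-fold and 5.66-fold.

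In the DNA methylation machinery 7 of 17 genes rose and 2 fell in naive cells, and 4 rose and 3 fell in memory cells (adjusted p = 0.240 and 0.351). UHRF1 rose at least 51.1-fold in naive cells, from a resting mean of 4.86, and 9.37-fold in memory cells and GADD45A 2.39-fold and 3.05-fold. DNMT1 rose 1.74-fold in naive cells (0.80 ± 0.15, adjusted p = 0.000104). In memory cells DNMT1 changed by 0.27 ± 0.13 (adjusted p = 0.123), by 0.35 (adjusted p = 0.0443) without memory replicate 2 at 48 h and by 0.25 (adjusted p = 0.0392) with donors as blocks. DNMT3A changed by 0.06 ± 0.13 and by 0.15 ± 0.12 (adjusted p = 0.761 and 0.354). CCR7 changed by 0.24 ± 0.18 in naive cells and rose by 0.50 ± 0.17 in memory cells (adjusted p = 0.332 and 0.0189), where it was 0.38 (adjusted p = 0.0787) without memory replicate 2 at 48 h. CD69, an early activation marker, fell by 0.78 ± 0.17 in memory cells (adjusted p = 0.000683). In naive cells it changed by -0.39 ± 0.19 (adjusted p = 0.103), by -0.52 (adjusted p = 0.0194) without naive replicate 1 at rest and by -0.53 (adjusted p = 0.0128) with donors as blocks.

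Transcripts of other blood cells fell in activated memory cells: S100A8 fell by 6.39 ± 0.81, LYZ, lysozyme, by 6.30 ± 0.75 and MMP8 by 5.96 ± 0.98 on the log2 scale (by 6.63 without memory replicate 4 at rest). S100A8 and MMP8 ended at means of 5.10 and 3.18, so their falls are lower bounds. Of 11 monocyte markers 9 fell (adjusted p = 0.00173), of 5 dendritic cell markers 5 (adjusted p = 0.0113) and of 4 neutrophil markers 3, and the first 2 lists had adjusted p = 0.340 and 0.317 with an estimated correlation. In naive cells LYZ also fell, by at least 4.44 ± 0.82 (by 3.74 without the array labelled naive replicate 6 at rest), and 2 of the 11 monocyte markers fell (adjusted p = 0.189).

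Activation changed 7420 genes in naive cells (4003 rose, 3417 fell) and 7455 in memory cells (3586 rose, 3869 fell). The groups did not overlap in 5529 and 4770 of all genes, where chance gives 0.952% and 0.253%, and 5366 and 4727 of these also passed the test. Of the genes past the threshold 2750 rose in both, where independent sets would share 800. Another 2497 fell in both, where they would share 737, and 74 went opposite ways. Log2 changes correlated across genes at r = 0.811 (Spearman 0.738), with the same caution on genes as replicates. The share of genes that rose in naive cells was 53.9%, and 40% after array medians were subtracted. The count in memory cells was 4404 with the monocyte score as a covariate.

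**Figure D4:**
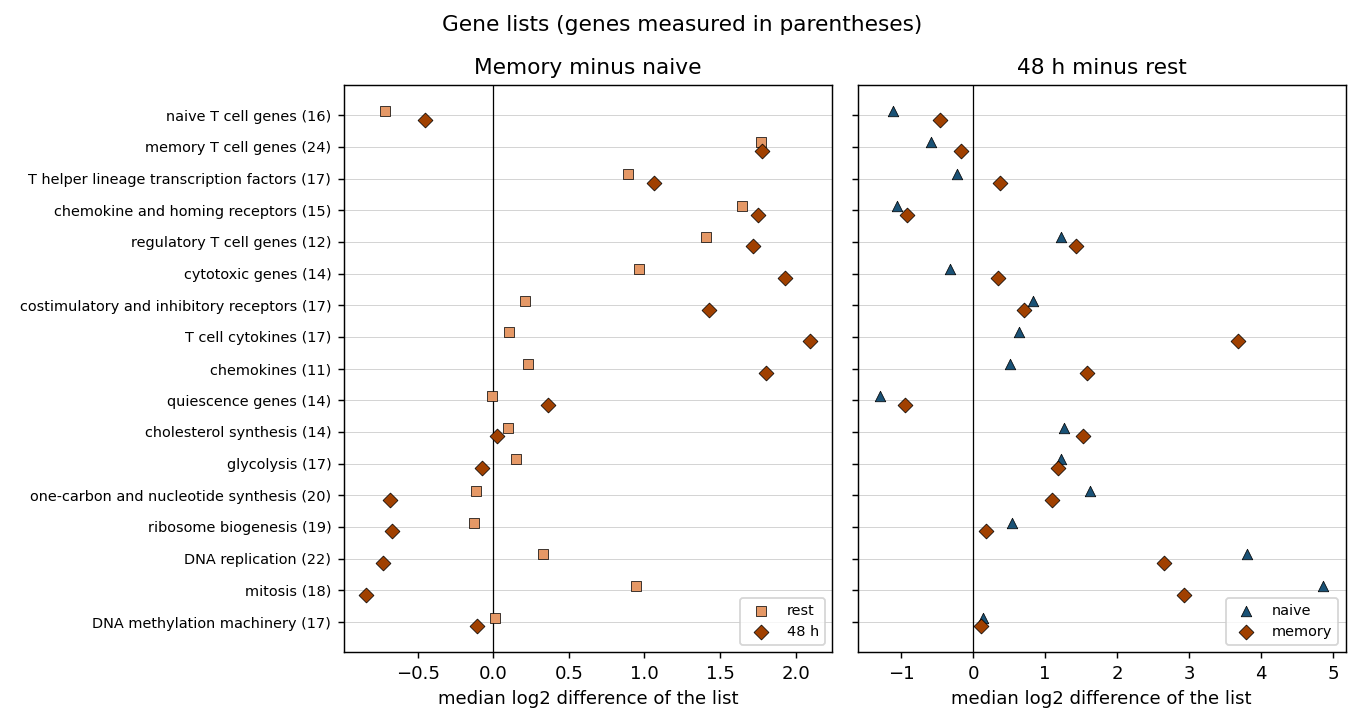
Median log2 difference of each gene list, memory minus naive cells on the left and 48 h minus rest on the right, with the number of genes measured beside the name and 1 symbol per comparison. Cytokine genes had a median of 0.10 at rest and 2.09 at 48 h between cell types, and mitosis genes 0.95 and -0.84.

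The last question was which responses to activation differ between the cell types, tested as the interaction of cell type and time. Cytokine genes rose more in memory cells: the difference of the changes was 5.95 ± 0.38 SE for IL17A, 5.48 ± 0.43 for IL22, 5.14 ± 0.44 for IL3 and 4.39 ± 0.24 for IL13 (n = 7, 6, 5 and 4), with adjusted p of 1.1e-07 or less. For IL17A, IL22 and IL3 the other 3 group means, and for IL13 both resting means, lay under 5.38, so these sizes are not exact. IL2 rose alike within its error (-0.35 ± 0.38, adjusted p = 0.618), also from 2 resting means under 5.38. For IFNG the difference was 1.78 ± 0.87 (adjusted p = 0.210), and 2.64 (adjusted p = 0.0269) without naive replicate 5 at 48 h. UHRF1 rose less in memory cells (-2.45 ± 0.42, adjusted p = 0.000659), as did TYMS (-2.24 ± 0.51, adjusted p = 0.00667) and IL2RA (-1.97 ± 0.54, adjusted p = 0.0210). MKI67 also rose less (-2.77 ± 0.76, adjusted p = 0.0211), with a value of -2.52 (adjusted p = 0.0529) without naive replicate 7 at 48 h. For UHRF1 and MKI67 the resting naive mean lay under 5.38, so these are lower bounds.

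Of 17 cytokine genes 10 had a larger and none a smaller change in memory cells (median 1.76, camera adjusted p = 4.9e-17; 11 adjusted over the list alone), and of 11 chemokines 4 had a larger one (median 1.08, adjusted p = 1.5e-05; 4 adjusted over the list alone). DNA replication genes had a smaller rise in 17 of 22 cases (median -1.08, adjusted p = 1.2e-16; 21 adjusted over the list alone). These 3 lists passed with an estimated correlation. Mitosis genes had a smaller rise in 17 of 18 cases (median -1.82, adjusted p = 1.1e-14, and adjusted p = 0.113 with an estimated correlation; 18 adjusted over the list alone). One-carbon and nucleotide synthesis genes had a smaller rise in 9 of 20 cases (median -0.57, adjusted p = 2.5e-07, and adjusted p = 0.0753 with an estimated correlation; 12 adjusted over the list alone), with MTHFD1 at -1.10 ± 0.13. Of 17 genes of the DNA methylation machinery 2 had a smaller change (median -0.06, adjusted p = 0.453). DNMT1 differed by -0.53 ± 0.20 (adjusted p = 0.0948, and 0.0146 with donors as blocks). SATB1, a chromatin organiser of naive T cells, fell in naive and rose in memory cells (1.93 ± 0.22, adjusted p = 7.6e-06). SLAMF7 and IRF8, genes that myeloid cells and activated lymphocytes express, had interactions of -4.98 ± 0.54 (a lower bound) and -4.23 ± 0.67, and MMP8 and CRISP3 of -5.14 ± 1.45 and -4.84 ± 1.28 (-6.17 and -5.79 without the array labelled naive replicate 6, and -5.80 for MMP8 without memory replicate 4 at rest), beside a median of -1.56 for the monocyte markers (adjusted p = 0.0250, and adjusted p = 0.576 with an estimated correlation). The sizes for MMP8 and CRISP3 are not exact, since only the resting memory mean lay above 5.38. SLAMF7 differed from these: it averaged 4.88 in resting naive cells and lay above 5.38 in the other groups, naive cells at 48 h among them.

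The interaction passed in 1896 genes, 694 with a higher and 1202 with a lower change in memory cells. In 879 of them the change had the same sign in both cell types and passed in both, in 497 it passed in naive cells alone and in 434 in memory cells alone, and in 74 it went opposite ways. The count was 3497 with donors as fixed blocks and 3174 with donors as random blocks. It was 1042 without the 4 memory arrays with high platelet markers and 1043 with the monocyte score as a covariate. The share with a higher change was 36.6%, 50.7% after a further quantile normalization and 58.7% after array medians were subtracted.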

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

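The tests of the 3 patterns below were chosen after the result was seen, and the splits of arrays into random groups were planned before. A single array that stood apart from its group, by a Dixon ratio (the gap to the next array over the range) past its 5% critical value, was found in 56 of 347 pairs of gene and group, where chance gives about 1 in 20. Of these, 39 belonged to the array labelled resting naive replicate 6: MMP8 0.911, GZMA 0.910, NOG 0.907, UHRF1 0.906, ENTPD1 0.885, CCR2 0.880, TNFRSF9 0.873, NHSL2 0.862, PRDM1 0.858, TPX2 0.853, MKI67 0.852, PCLAF 0.845, TIGIT 0.842, S100A12 0.840, MAF 0.830, IFNG 0.829, TOP2A 0.820, IL2RA 0.806, LRRN3 0.802, IL12RB2 0.778, CRISP3 0.775, CDK1 0.769, TYMS 0.729, HLA-DQB1 0.713, AK5 0.710, CCR7 0.706, SATB1 0.704, GZMK 0.693, PECAM1 0.681, DTL 0.679, CST7 0.679, SLC1A5 0.665, CCR4 0.658, PCSK5 0.653, FCRL3 0.648, RRM2 0.645, IL18RAP 0.634, ANTXR2 0.632 and IL22 0.630.

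The other 17 ratios were FOS 0.705 and CD69 0.702 in resting naive replicate 1, and IL13 0.659 in resting naive replicate 5, a dim gene there. FOS and CD69, both genes induced by handling of cells, were lowest in that replicate 1. They had 8.60 and 11.1 there, against means of 11.6 and 11.8 in the other resting naive arrays. In resting memory cells they were XKRX 0.645 in replicate 1, CCL3 0.646 and GADD45A 0.605 in replicate 3 and PFKM 0.613 in replicate 5. In naive cells at 48 h they were CXCR6 0.966 and PNOC 0.869 in replicate 3, PCLAF 0.833 in replicate 4, CCL4 0.870 in replicate 5 and WDR12 0.836 in replicate 7. In memory cells at 48 h they were TOP2A 0.853, CXCR6 0.823 and IL22 0.812 in replicate 2, UHRF1 0.715 in replicate 4 and ENTPD1 0.791 in replicate 7. With 17 of 347 this is near the share chance gives.

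The response to activation differed between the cell types in 1896 genes. Among named genes the change was larger in memory cells for IL17A 5.95, IL22 5.48, IL3 5.14, IL13 4.39, CCL3 4.24, PNOC 3.98, SATB1 1.93, MAF 2.84, CXCR6 1.45, GZMB 2.79, IL1R2 2.57, TNFRSF4 2.05, PIK3IP1 1.18, IFIT2 1.65 and BATF3 1.92, and smaller for MMP8 -5.14, SLAMF7 -4.98, CRISP3 -4.84, S100A12 -4.67, IRF8 -4.23, MPEG1 -4.02, IL2RA -1.97, UHRF1 -2.45, TYMS -2.24, MKI67 -2.77, PFKM -0.81, MTHFD1 -1.10, BOP1 -0.93 and SLC1A5 -1.66. Without the array labelled resting naive replicate 6 the interaction was -5.63 for S100A12 and -4.64 for MPEG1. Of these genes IL17A, IL22, IL3, PNOC, MMP8, CRISP3 and S100A12 had 3 group means under the lowest array median of 5.38, IL13, CCL3, IL1R2, CXCR6 and MPEG1 had 2 and SLAMF7, UHRF1 and MKI67 had 1, so the sizes are not exact. The CXCR6 value, with an adjusted p of 0.0487, lost its call when any 1 of 16 of the 22 arrays was left out. Probe sets without a gene name in the table used here passed the same threshold in 81 cases at rest, 144 at 48 h, 2595 and 1705 for activation of naive and memory cells and 54 for the interaction; what they measure was not analysed here.

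The array labelled resting naive replicate 6 had the profile of resting memory cells. On a scale from the other naive arrays (0) to the memory arrays (1) the naive and memory list genes had a median position of 1.001, with 1.02 over 11 naive and 0.983 over 24 memory genes, which met the prediction for memory cells under a naive label. A mixture with mostly naive cells was excluded by a naive share of -0.0391 (quartiles -0.0715 and 0.0215). A swap with a resting memory array was excluded as well, since the highest naive share of the 7 was 0.0582, against 0.933 for the lowest of the other naive arrays. The donor was not settled. By correlation of deviations the memory array of the same number ranked 5 of 7 (0.00558), and the highest was donor 7 (0.480). Memory replicates 2, 5 and 6, the resting arrays with high platelet markers, had the lowest correlations (-0.126 to 0.00558). The array itself had a low mean of the platelet markers (5.16), as had memory replicate 7 at rest (4.85). The ranking cannot separate donor from platelet content, so it points to no donor.

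Genes of granulocytes and monocytes were high in resting memory arrays. The mean of MMP8, CRISP3, S100A12, S100A8, LYZ and CYBB followed the neutrophil markers across the 7 arrays at r = 0.952 (permutation p = 0.000595, adjusted p = 0.00238 over 4 relations; Spearman 1; 0.946 without the 2 farthest arrays), which met the prediction for granulocytes left among the selected cells. Of these 6 genes S100A12, S100A8 and LYZ are also in the monocyte list. The relation of the 6 to that list was not tested, so granulocytes are not singled out. The memory T cell gene mean moved by 0.208 where the range of the monocyte markers needed 2.03, a share of 0.102. This spoke against cells with those markers as the main source of the memory T cell genes. The 2 means correlated at r = 0.533 (permutation p = 0.218, adjusted p = 0.436, Spearman 0.571, 0.480 without the 2 farthest arrays). A smaller part, or a part in single genes, was not excluded. The neutrophil markers were not used in that test. Transcription of the 6 genes by memory T cells remained open, as their SD between arrays was 19.6 times that of the memory T cell genes and no bound had been set.

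Cell division genes were higher in resting memory cells and rose less with activation. Dividing granulocyte precursors were first tested by the correlation of mitosis genes with neutrophil markers (r = 0.156, permutation adjusted p = 0.722, Spearman 0.286, 0.191 without the 2 farthest). With 7 arrays this correlation is too imprecise to decide. After that value was seen the test was replaced by the share of the needed change, 0.306 (0.653 of 2.13), with a bound also set afterwards. The share lay under that bound, which spoke against such precursors as the main source of the mitosis genes. A smaller part was not excluded. The prediction for a ceiling of the signal near the top of the arrays' range was not met. The mean difference at 48 h was -0.86, and the highest group mean 11.3 lay under the highest value of 13.6. A lower ceiling of single probe sets cannot be judged from the highest value of other genes, so it was not excluded. A dividing fraction with regulatory T cell genes remained open (r = 0.417, adjusted p = 0.477; Spearman 0.321; -0.774 without the 2 farthest).

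The real grouping gave the highest count of 100 splits in 4 comparisons, where the count was matched by 1 split, the real one, each time. The highest other counts were 1294 at rest, 2707 at 48 h and 5006 and 4406 for activation. For the interaction 2 splits reached the count, with 1939 in the highest other one. Among splits that part the pairs of donors the real one alone reached the count, 1 of 64 at rest (highest other 1674) and 1 of 32 for activation of memory cells (4431). The 48 h comparison and the activation of naive cells have 16 such splits each, too few to reach 5%.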

How the results depend on the processing

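The cause of these shifts was not tested unless stated. Donors as fixed blocks gave 3497 genes for the interaction and 1180 for the same direction at rest and 48 h, and changed no call of a named gene or list other than those given beside it; donors as random blocks gave 3174 for the interaction and changed the same named calls except that of DNMT1 in activated memory cells. The 4 donors with all arrays gave 1268 for the same direction. Array weights gave 3447 at rest. A 2-fold minimum gave, by construction fewer, 663 at rest, 793 at 48 h, 2779 and 2246 for activation of naive and memory cells, 673 for the interaction and 222 for the same direction. With 1 array left out the same-direction count went from 599 (resting naive replicate 4) to 1146 (resting naive replicate 6). The mitosis list at 48 h was also refitted without each array, chosen after seeing the data, as was the correlation between sample numbers without resting naive replicate 6.

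Other planned fits changed these calls of named genes. With the groups of a contrast alone TNF at rest (adjusted p = 0.0947), DNMT1 at 48 h (0.0775) and IFNG for activation of naive cells (0.0858) lost their call and IL2RA at 48 h passed (0.0171). DNMT1 at 48 h was also lost with array weights (0.0817) and a further quantile normalization (0.0501). The CXCR6 interaction was lost with these 2 (0.0529 and 0.0609), a trended and robust prior (0.0532) and every probe set (0.0501), and that of PFKM with array medians subtracted (0.0554) and in the 4 donors (0.0513). In the 4 donors CD69 passed at rest (0.35, adjusted p = 0.0223), at 48 h (-0.34, 0.0161), for activation of naive cells and for the interaction (-0.70, 0.00390), as did CCR7 (0.00332) and IL2RA (0.36, 0.0265) at 48 h and DNMT1 for activation of memory cells (0.00457). Array weights gave calls to CCR7 at 48 h, CD69 in naive and DNMT1 in memory cells for activation, and subtracted medians to CD69 in naive cells.

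With fry, which tests a list by itself and not against other genes, 17 pairs of list and comparison passed that had not with camera, among them the DNA methylation machinery for activation (adjusted p = 6.5e-05 in naive and 0.00366 in memory cells) and cytokines (1.6e-05) and chemokines (8.6e-06) for activation of naive cells. Lost were 5: ribosomal proteins (0.0826), interferon response (0.113) and platelet markers (0.121) at rest and the memory T cell genes (0.251) and monocyte markers (0.117) for the interaction.

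The fit without the 4 memory arrays with high platelet markers was chosen after seeing the data. It gave 995 at rest, 1042 for the interaction and 387 for the same direction. The mean of the platelet list at rest went from 1.47 to -0.24, by construction of the choice. In that fit 15 pairs of named gene and comparison lost their call, and all kept their sign. At rest these were TNF, GADD45A (0.55, adjusted p = 0.0871) and DNMT3A (-0.35, adjusted p = 0.110). ENTPD1 and DNMT1 at 48 h and LRRN3 and CCR7 for activation of memory cells were also lost. So were the interactions of MMP8 (-4.94), CRISP3 (-4.58), S100A12 (-4.66), MPEG1 (-3.31), CXCR6 (1.17), IL2RA (-1.99, adjusted p = 0.0778), MKI67 (-2.35, adjusted p = 0.0962) and SLC1A5 (-1.37). The interaction of the glycolysis, monocyte and dendritic cell lists lost its call as well, and the naive T cell genes passed for activation of memory cells. Blocks without resting naive replicate 6 gave 3749 at rest, 3705 for the interaction and 1383 for the same direction, and IL2 passed at rest (0.67, adjusted p = 0.0180). The monocyte score as a covariate, which differs between the groups (means 6.01 and 8.72 at rest), gave 0 at rest and 0 for the same direction in limma, with 1032 genes at an unadjusted p under 0.05 at rest, 4404 for activation of memory cells and 1043 for the interaction. Of 208 pairs of named gene and comparison 56 lost their call, and the median of the memory T cell genes went from 1.77 to 0.72 at rest, from -0.17 to 1.17 for activation of memory cells and from 0.22 to 1.13 for the interaction. TNF at rest then had -0.17 and, for activation of memory cells, MMP8 0.76, CRISP3 0.64 and CYBB 0.42.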

Other observations

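Of 20 cytokine receptors 10 were higher and 3 lower in resting memory cells (median 0.55, adjusted p = 0.000281, and 0.0962 with an estimated correlation), with IL18RAP at least 7.03-fold higher, and 5 of 17 costimulatory and inhibitory receptors were higher (median 0.21, adjusted p = 0.000173, and 0.0599). Quiescence genes were higher in memory cells at 48 h in 6 of 14 cases (median 0.36, adjusted p = 6.3e-05), which passed with an estimated correlation, and PIK3IP1, an inhibitor of PI3-kinase, fell less in memory cells (1.18 ± 0.26). Interferon response genes were higher at 48 h in 8 and lower in 1 of 19 cases (median 0.48, adjusted p = 0.00268, and 0.348 with an estimated correlation), and IFIT2 rose more in memory cells (1.65 ± 0.39). Unfolded protein response genes were higher in 2 of 13 cases (median 0.32, adjusted p = 0.00116, and 0.221) and apoptosis genes in 6 and lower in 2 of 12 (median 0.54, adjusted p = 0.00406, and 0.120). T cell receptor signalling genes fell in 12 and rose in 2 of 21 cases in naive cells (median -0.45, adjusted p = 0.00453, and 0.129). STAT and SOCS signalling genes rose in 9 and fell in 3 of 14 cases in memory cells (median 0.41, adjusted p = 0.0158, and 0.0962).

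Ribosomal protein genes had medians between -0.10 and 0.06 in the 5 comparisons. At rest 1 of 15 was lower (adjusted p = 0.0468, and 0.562 with an estimated correlation), and 3 fell in the activation of naive cells (adjusted p = 0.199). At rest 2 of 10 B cell markers were higher (3 higher and 3 lower adjusted over the list alone) and their median was 0.07 (adjusted p = 0.493, fry mixed test 0.00233). One handling stress gene was higher, 1 of 2 CD8 T cell markers was lower, and no natural killer cell or erythroid marker passed. The 6 natural killer cell markers had a median of -0.06 (adjusted p = 0.476), 6 erythroid markers of 0.01 (adjusted p = 0.501) and 7 handling stress genes of 0.05 (adjusted p = 0.590). With donors as blocks, chemokines at rest (2 of 11 higher, median 0.23, adjusted p = 0.0324, and 0.111 with an estimated correlation) had an adjusted p of 0.0551, amino acid transport and stress response genes at 48 h (3 of 15 lower, median -0.30, adjusted p = 0.0782) of 0.0490 and platelet markers in the activation of memory cells (2 of 8 fell, median -1.74, adjusted p = 0.0820) of 0.0381. Without the array labelled resting naive replicate 6 the interaction of the memory T cell genes (median 0.22, adjusted p = 0.00785) had an adjusted p of 0.490, that of the T helper lineage transcription factors (0.60, 0.00529) of 0.0736 and that of T cell receptor signalling (0.23, 0.0224) of 0.0536. With an estimated correlation the 3 lists had adjusted p = 0.634, 0.334 and 0.239. In the activation of naive cells without it, costimulatory and inhibitory receptors (adjusted p = 0.0734) had 0.0185 and STAT and SOCS signalling (adjusted p = 0.0685) had 0.0456.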
